A study of Homo sapiens with 16 samples.

How the data were processed

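Chromatin immunoprecipitation with sequencing was carried out by the authors on H9 human embryonic stem cells at day 7 of differentiation, in biological duplicate per the labels. Peak lists were used for H3K9me3 in wild-type and AHDC1 knockout cells, 2 libraries each, and for Gibbin in 2 libraries from a line with an inducible Gibbin and biotin-ligase fusion. The Gibbin cells were given doxycycline for 24 hours and 5% 1,6-hexanediol for 60 seconds, per the labels' protocols; the peak names carry 60 for replicate 1 and 75 for replicate 2, and which applies to replicate 2 could not be settled. The other 10 samples of the series were not used here. Groups were taken from the sample titles.

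Peaks were called by the authors with MACS2, with bedtools and SAMtools also named, on hg38, per the submitters' processing notes, which give no versions. The aligner, control library and calling threshold are not given in the sources used here. Peaks were called per library, as the peak names show. The deposited values are a score, the fold enrichment (a ratio over the caller's background), −log10 p and −log10 q for each peak, and for Gibbin also the summit position. Each deposited list was found to be sorted by −log10 p and to end at exactly 100000 peaks. In the H3K9me3 lists 133 and 35780 wild-type peaks and 53641 and 74921 knockout peaks share the list's lowest p and stand in chromosome order. A q-value of 1 is held by 93.4% and 96.6% of the wild-type and 96.5% and 99.4% of the knockout peaks. No read counts are given, so the depth is unknown and no counting intervals were computed.

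Gene positions were taken from the RefSeq gene table of GRCh38.p14, for 19970 protein-coding genes on the autosomes and chromosome X, without strand. A window around transcription start sites had been planned; without strand, windows of 1 kb around both ends of each gene took its place, and 5 kb around both ends took the place of a start-site window in the H3K9me3 alternative. No genome sequence was at hand, so the planned stratification by CpG content could not be run, nor could repeats be examined. Peaks on unplaced sequences, chromosome Y and the mitochondrial genome were left out of the comparisons. Chromosome lengths for circular shifts were the largest coordinates seen, and shifted peaks can fall in assembly gaps.

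For H3K9me3, agreement was the Jaccard index in bp for the 6 pairs of libraries, checked against bedtools 2.31.1. Regions were the merged union of the 4 lists, present in a library where a peak overlapped by 1 bp, and counts were set beside the 2 other splits of the 4 libraries. Genes were compared by the percent of the body plus 2 kb on each side that peaks covered, for genes with a mean covered length of at least 1000 bp, with limma 3.58.1 (trend, R 4.3.3) and Benjamini-Hochberg adjustment at 0.05. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and with an estimated one. For each list and library, the summed width of peaks with their middle in the list's gene regions was set against circular shifts. There were 1000 shifts for the best 20000 peaks and 100 for the whole lists. The percent of a list's summed gene length covered was also computed for each library. The p-values of limma for single genes measure the spread between these libraries, which the labels call biological duplicates. Camera sets list members against the other genes, and the shifts were made within each library. The p-values of those tests do not measure the spread between libraries.

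For Gibbin, common peaks were peaks of replicate 1 overlapping replicate 2 by 1 bp. Replicate overlap was set against 100 circular shifts, and the share at gene ends and on H3K9me3 regions against 1000, as two-sided permutation tests. The lists were tested with Fisher's exact test, two-sided, and nearness to H3K9me3 regions with the Cochran-Mantel-Haenszel test over 5 width quintiles and against 200 shifts. Genes and regions that neighbour each other are not independent, so these p-values are too small. Intervals were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures drawn with matplotlib 3.10.9.

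There were 19 lists, named in the report, of which 1 symbol (H19) was not among protein-coding genes. Genes were named by a rule: for H3K9me3 the 10 in each direction with the largest difference past the threshold, filled up with genes at which the libraries of the 2 genotypes do not overlap; for Gibbin genes among the 10 best mean ranks; 4 members of each list past the threshold; and 6 genes always given. Design, lists, rule and most alternatives were set before the data were examined. The best 20000 peaks, all above the tied values, and the other alternatives described as added were chosen after seeing the data. Alternatives were stricter lists, merging, overlap and distance definitions, scaling, filters, gene windows, a log2 scale, a replicate block, and each library left out.

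The tests were tested on simulated data. In coverage simulated for the best 20000 peaks with the spread of the real libraries, limma recovered 0% of 200 genes of any baseline raised by 5, 20, 40 or 60 percentage points, so a count of 0 genes says little. A second simulation, set up because a first one had recovered none, raised 200 genes with a baseline under 30% covered: 32%, 50%, 62% and 86% were recovered at those steps, with 8 false calls among 1601 unchanged genes. With 0.1 times the spread, 80% were recovered at 5 and 100% at the larger steps, with 4 false calls among 1603. Beside raised genes, a list of unchanged genes had camera (limma) p-values between 0.0112 and 0.0555. In the Gibbin test of gene ends, 0 of 20 simulations with no planted peaks and 20 of 20 with 2% planted were called. The list test called a raised list in 93 of 100 simulations and 10 of 1700 unchanged lists. All of these simulations drew genes and peaks independently of their neighbours. They therefore cannot show how often the tests make false calls when neighbouring genes or peaks are alike.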

Results

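The series concerns Gibbin, the protein encoded by AHDC1, in H9 cells, an established human embryonic stem cell line, taken through 7 days of differentiation. Chromatin immunoprecipitation with sequencing was analysed here for 6 of the 16 samples. They comprise 2 wild-type and 2 AHDC1 knockout libraries for H3K9me3, a histone mark of silent chromatin, and 2 libraries for Gibbin itself in H9 cells carrying an inducible biotin-ligase fusion. Libraries for CTCF and GATA3 and for Gibbin in undifferentiated cells were not analysed here. Each list holds exactly 100000 peaks called in 1 library, and no read totals, so the sequencing depth is unknown. The H3K9me3 lists cover 46.3 Mb and 76.5 Mb in wild type and 67.8 Mb and 46.9 Mb in knockout, and the Gibbin lists cover 66.0 Mb and 301 Mb. Few H3K9me3 peaks pass a q-value of 0.05, namely 225 and 121 in wild type and 122 and 26 in knockout. The weakest peaks of 3 of the H3K9me3 lists share a single p-value and are kept in chromosome order, so values are given for the whole lists and for the best 20000 peaks of each library, which lie above these ties.

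**Figure D1:**
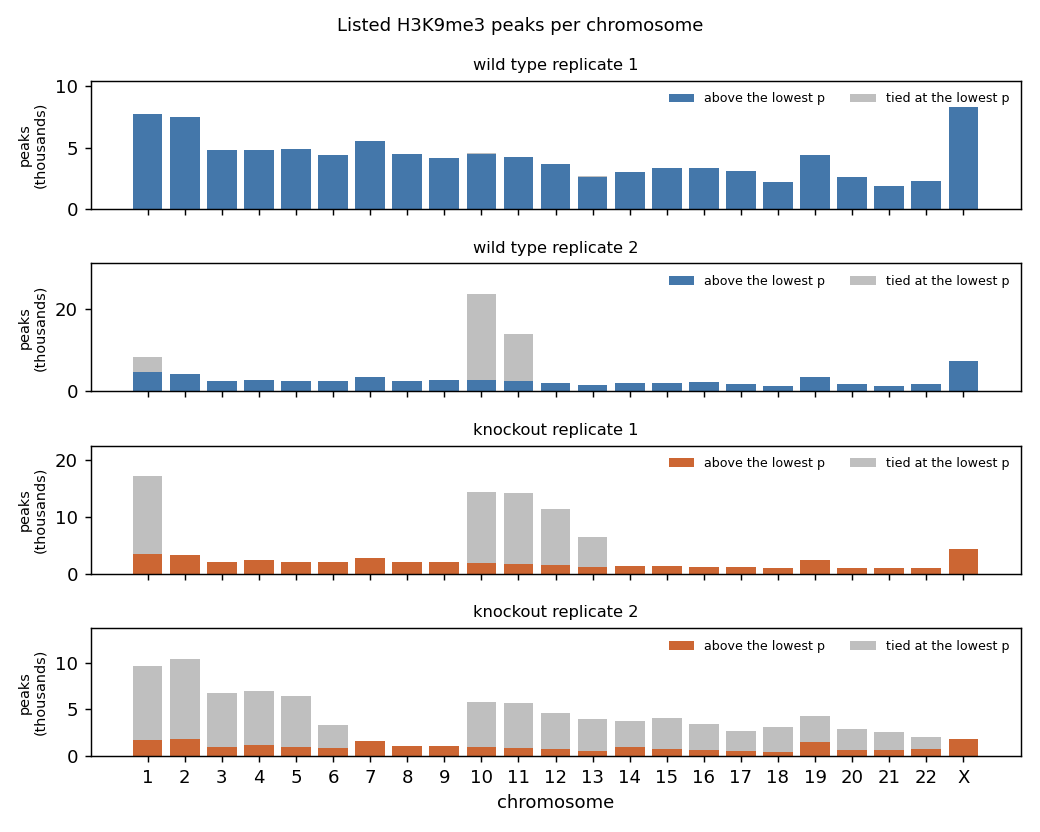
Number of listed H3K9me3 peaks (y axis, in units of 1000, with its own scale in each panel) on each chromosome (x axis) in the 4 libraries. Grey parts are peaks tied at the list's lowest p-value, which make up 0.133% and 35.8% of the wild-type lists and 53.6% and 74.9% of the knockout lists; where they end, later chromosomes of the sorted list have none.

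In both genotypes H3K9me3 was concentrated on the clustered protocadherin genes, which encode cell adhesion molecules of neurons. Among the best 20000 peaks, the summed width of peaks centred on them was set over that of circularly shifted peaks. The ratio was 55.4 ± 3.73 (SD, n = 2) in wild type and 48.7 ± 3.45 (SD, n = 2) in knockout. Zinc finger genes, a large family of DNA-binding proteins, had ratios of 1.69 ± 0.115 in wild type and 3.97 ± 0.622 in knockout, and olfactory receptor genes had ratios of 3.91 ± 1.02 and 4.01 ± 0.938. Protein-coding genes as a whole held less peak width than after shifts, with a ratio of 0.754 ± 0.0361 (SD, n = 4). In permutation tests against 1000 shifts, the protocadherins reached the smallest p they can give, 0.001, in every library (largest adjusted p = 0.00999), while the largest adjusted p among the wild-type libraries was 0.190 for zinc finger genes. The whole lists gave the protocadherins a smaller mean ratio of 19.2, from 15.6 to 24.2. Wild-type replicate 2 did not pass there (permutation test against 100 shifts, adjusted p = 0.0792), while zinc finger genes passed in every library at a mean of 2.61 (largest adjusted p = 0.0495). The 78 regions with a q-value of 0.05 or less in both wild-type libraries all had a peak among the best 20000 of both knockout libraries, and the 21 such knockout regions all had one in both wild-type libraries. The strongest shared regions, 18 in the 4 libraries, included 1 at OR2T1 (chromosome 1, 248405573 to 248409132), 1 at FRG2C (chromosome 3, 75666415 to 75672611) and 1 at PTPRN2 (chromosome 7, 158146922 to 158149664), in hg38.

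The comparison of knockout with wild type asks where loss of Gibbin goes with a different H3K9me3 pattern. Zinc finger genes carried more H3K9me3 in both knockout libraries than in either wild-type library among the best 20000 peaks. Over the whole lists, wild-type replicate 2 and knockout replicate 2 lay close together. Among the best 20000 peaks, 6.10% ± 0.715 (SD, n = 2) of the summed length of the 517 zinc finger genes was covered in knockout against 1.88% ± 1.07 (SD, n = 2) in wild type, a ratio of 3.25. The libraries had 1.12% and 2.63% in wild type and 5.60% and 6.61% in knockout. The values over the whole lists were 10.5% ± 1.75 and 7.49% ± 2.13, a ratio of 1.40. There the summed width of peaks centred in these genes was 1.38e+06 and 2.10e+06 bp in wild-type replicates 1 and 2. It was 2.70e+06 and 2.13e+06 bp in knockout replicates 1 and 2. The 250 zinc finger genes of chromosome 19 had a ratio of 3.32, while the 1168 other genes of that chromosome had 0.892 and all protein-coding genes 1.40, all among the best 20000 peaks. Both ratios for chromosome 19 depend on the library, with 1.63% and 3.91% in wild type and 8.47% and 9.93% in knockout for its zinc finger genes, and 0.702% and 2.47% against 1.57% and 1.26% for its other genes. Counted as peaks rather than length, 2.11% and 2.31% of the best 20000 peaks lay in zinc finger genes in wild type and 3.38% and 4.41% in knockout. Wild-type replicate 1 had narrower best peaks, with a median width of 199 bp against 558 bp in wild-type replicate 2 and 717 and 630 bp in knockout. Its share was near that of replicate 2 by peaks but not by length, so the ratio of 3.25 rests in part on peak width. The libraries also separated in the best 5000 (1.78% and 1.60% against 3.04% and 3.38%) and the best 10000 (2.04% and 2.14% against 3.52% and 4.16%). They did not in the best 1000 (1.60% and 0.400% against 0.7% and 1.10%) or the best 2000 (2.05% and 0.850% against 2.05% and 2.05%), so the difference lies in peaks below the strongest. Lists of fixed length give relative values, and with all tied peaks left out the libraries overlapped, the lower knockout value standing -1.21 percentage points from the higher wild-type value.

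**Figure D2:**
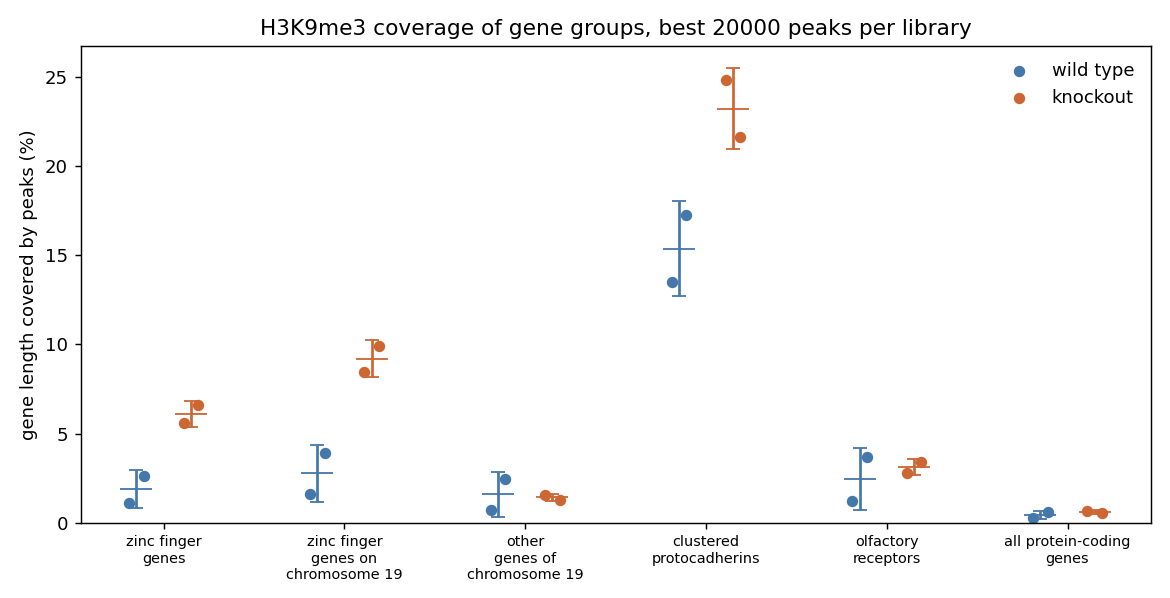
Percent of summed gene length covered by H3K9me3 peaks (y axis) for 6 gene groups (x axis), among the best 20000 peaks of each library. Points are libraries, horizontal bars means and whiskers SD (n = 2 per genotype); for zinc finger genes both knockout points, 5.60% and 6.61%, lie above both wild-type points, 1.12% and 2.63%.

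Tested as a list fixed before the data were examined, zinc finger genes were higher in knockout by a mean of 16.1 percentage points over 202 genes among the best 20000 peaks (limma's camera with a preset correlation, adjusted p = 4.86e-24). With an estimated correlation the adjusted p was 0.158. Only genes with a mean covered length of at least 1000 bp over the 4 libraries are tested. A gene without a wild-type peak therefore entered through knockout alone, which can raise the mean difference of the tested members. The summed length of all 517 zinc finger genes, given above, showed a smaller difference. Over the whole lists the mean difference was 7.61 percentage points over 313 genes (camera, adjusted p = 1.46e-18, and adjusted p = 0.776 with an estimated correlation). Leaving out 1 library at a time, it ran from 4.66 without wild-type replicate 1 to 10.5 without wild-type replicate 2. Those on chromosome 19 gave 15.6 percentage points over 117 genes (camera, adjusted p = 2.55e-17, and 0.158 as the adjusted p with an estimated correlation) and, over the whole lists, 7.97 over 179 genes (camera, adjusted p = 1.31e-18, and adjusted p = 0.776 with an estimated correlation). No single member passed limma's test, adjusted over all genes or adjusted over the list alone (0 in each direction). The largest differences in the best 20000 were at ZNF32 (chromosome 10, 43643862 to 43648881), covered 69.7% ± 1.54 in knockout and 1.86% ± 1.45 in wild type, and at ZNF879 with 72.4% ± 14.7 and 5.09% ± 7.19. ZNF132 had 66.4% ± 15.8 and ZNF551 66.1% ± 2.97, both without a wild-type peak of that rank (SD, n = 2 each). ZNF772, ZNF84 and ZNF12 followed, with differences of 64.8, 64.7 and 62.9 percentage points, as did ZIK1, a zinc finger gene outside the list, with 61.7. ZNF134 had 81.5% ± 8.83 in knockout and 31.6% ± 44.7 in wild type, a difference of 49.9 that fell to 18.3 without wild-type replicate 1. With weaker peaks included, the differences were 30.8 for ZNF32, 34.9 for ZNF879, 16.4 for ZNF551 and -1.54 for ZNF132. Wild-type replicate 2 had a peak over most of ZNF772, ZNF551 and ZIK1, at ranks 21326, 22653 and 29561, below the best 20000. The differences of these genes among the best 20000 therefore depend on that cut. Over the whole lists the leading members were ZNF300, ZNF891, ZNF354C and ZNF140, with differences of 54.7, 46.9, 38.3 and 37.2 percentage points, and on chromosome 19 ZNF677, ZNF649, ZNF302 and ZNF470, with 35.4, 34.8, 33.9 and 31.7, the last at 11.5 without wild-type replicate 1.

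**Figure D3:**
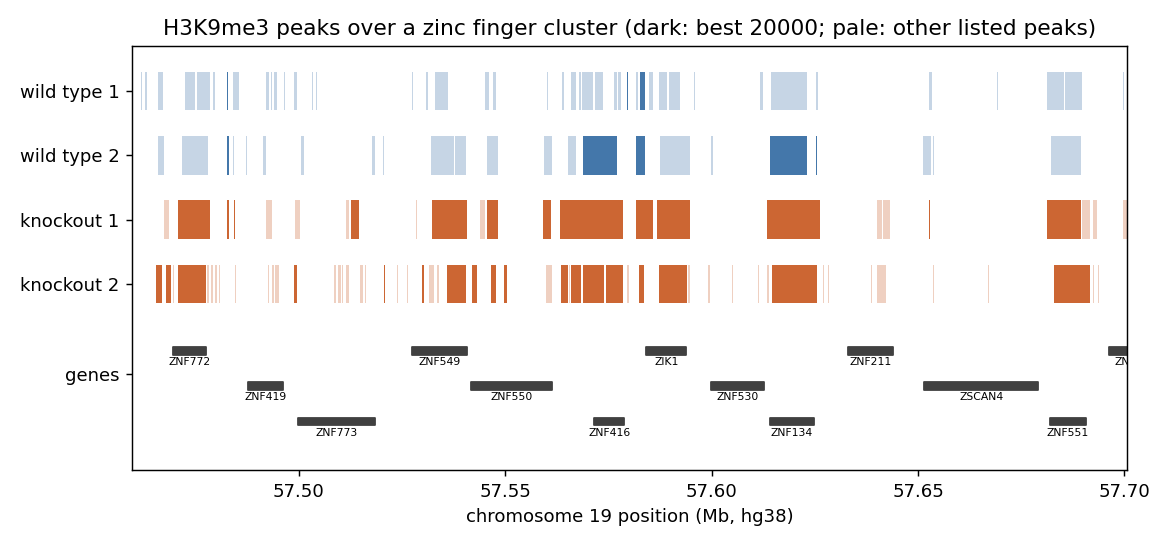
H3K9me3 peaks of the 4 libraries (bars, 1 line per library) over a zinc finger cluster of chromosome 19 from 57459586 to 57700648 in hg38 (x axis, Mb), with protein-coding genes below. Dark bars are among the best 20000 peaks and pale bars are other listed peaks. ZNF772 and ZNF551 have dark bars in both knockout libraries and in neither wild-type library, where pale bars mark weaker peaks. In wild-type replicate 2 these include peaks over most of each gene at ranks 21326 and 22653, just below the best 20000.

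The clustered protocadherins were higher in knockout by 9.90 percentage points over 43 genes among the best 20000 peaks (camera, adjusted p = 3.36e-09, and adjusted p = 0.306 with an estimated correlation). The difference over the whole lists was 9.28 over 47 genes (camera, adjusted p = 4.95e-19, and adjusted p = 0.776 with an estimated correlation). Their covered length was 23.2% ± 2.26 in knockout and 15.4% ± 2.67 in wild type (SD, n = 2), but the number of peaks on them was alike, 50 and 50 in wild type and 49 and 51 in knockout. Scaled to the covered length of each library, the best 20000 peaks gave 3.47 percentage points (camera, adjusted p = 0.749). The preset correlation treats members as nearly independent, but neighbours can share bases. With 2 kb on each side, the windows of PCDHB2 and PCDHB3 overlap. PCDHB2 and PCDHB3 differed by 51.8 and 50.3 percentage points, PCDHB10 and PCDHB15 by 25.7 (7.02 without knockout replicate 2) and 24.6, and PCDHB5, over the whole lists, by 23; none passed limma's test. Germline genes were lower in knockout over the whole lists by a mean of -12.5 percentage points over 14 genes (camera, adjusted p = 0.0476, and adjusted p = 0.838 with an estimated correlation), with CTAG2, MAGEA1, MAGEB2 and MAGEA4 at -51.1, -44.3, -34.9 and -18.6. That mean rested on single libraries, at -3.19 without wild-type replicate 2, -5.22 without knockout replicate 2, -19.9 without knockout replicate 1 and -23.4 without wild-type replicate 1, and passed only in the last (camera, adjusted p = 0.0150, and 0.845 with an estimated correlation). Its genes moved likewise, MAGEA4 to 0.67, MAGEB2 to -12.5 and MAGEA1 to -24.5 without wild-type replicate 2. These 4 genes lie on chromosome X, where 8.05% ± 0.655 of the wild-type lists and 3.08% ± 1.78 of the knockout lists fell (SD, n = 2), against 8.25% ± 1.65 and 7.17% ± 0.166 of the best 20000 peaks. The germline list had too few covered members to be tested among the best 20000 peaks.

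The other lists tested over the whole peak lists did not pass. Camera gave adjusted p = 0.0926 for olfactory receptors. They did pass as higher in 7 other settings, among them without wild-type replicate 2 (camera, adjusted p = 9.21e-06), but in none with an estimated correlation (adjusted p = 0.902 in that setting), and not in the best 20000 peaks (adjusted p = 0.922). In 1 of the 7, without knockout replicate 1, their mean difference was -0.36. The adjusted p was 0.647 for imprinted genes and for mesoderm regulators, 0.411 for mesenchyme and dermal matrix, and 0.236 for surface ectoderm and epidermis. Camera gave 0.458 for trophoblast and amnion, 0.236 for DNA methylation machinery and readers and for the BMP, WNT and retinoic acid response, 0.247 for H3K9 methylation machinery and 0.821 for CTCF and cohesin. HOX, ribosomal protein, pluripotency, neural and endoderm genes had fewer than 5 covered members and were not tested. HOX genes had 5 without knockout replicate 2 and passed there (camera, adjusted p = 0.00251, and 0.706 with an estimated correlation), but not with 5 genes by gene ends or 37 without the filter (adjusted p = 0.712 and 0.755). Of these lists, 1 gene was lower in knockout when adjusted over the list alone, LMX1B of the mesoderm regulators, a limb and kidney transcription factor on chromosome 9 (3.41% ± 0.226 in wild type, no peak in knockout; limma, adjusted p = 0.790 over all genes).

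Gene by gene, limma found 0 genes higher and 0 lower in knockout among 5305 genes over the whole lists, with 138 and 147 at an unadjusted p under 0.05. These became 20 and 514 without wild-type replicate 1, 456 and 75 without knockout replicate 2, and 41 and 296 with tied peaks left out. Among the best 20000 peaks it found 0 higher and 4 lower of 1803 genes, with 267 and 10 at an unadjusted p under 0.05. That imbalance rests on wild-type replicate 1, as the counts without it were 104 and 118. The 4 are neighbouring uncharacterised genes, LOC124901645, LOC124901650, LOC124901798 and LOC124901644, between 63752348 and 63756760 on chromosome 7. With 2 kb on each side the windows of these genes overlap, so the 4 calls share bases and are not separate findings. The genes are therefore better read as 1 place. They were fully covered in wild type and at 96.8%, 93.4%, 93.4% and 93.7% in knockout, so the differences are a few percent of length with almost no spread between replicates (limma, adjusted p = 0.041 for the first and 0.0013 for the others). Both knockout libraries lay above both wild-type libraries at 624 genes (34.6%) among the best 20000 peaks and below them at 119 (6.60%), where chance gives 33.3% in both directions together; over the whole lists the counts were 993 (18.7%) and 1009 (19%).

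Genes named next did not pass limma's test (adjusted p from 0.178 to 0.790) and are given for their size. TUG1, known for its long RNA (chromosome 22, 30969265 to 30979395), had the largest knockout coverage gain of either set, 80.8% ± 5.48 against no peak in wild type among the best 20000, and 87.1% ± 3.45 against 24.2% ± 7.80 over the whole lists (SD, n = 2). TAF7, a subunit of the general transcription factor TFIID that lies within the protocadherin clusters, had 58.9% and 3.05% among the best 20000. ZFP37, OR4C12, OR5L2, OR2T5 and OR2T34 differed over the whole lists by 56.2, 49.9, 43.4, 43.0 and 39.1 percentage points, the last at 21.3 without wild-type replicate 1. Lower in knockout among the best 20000 were OR10H2, PRR20D, MBD3L4, SLC38A5, GOLGA6L6 and KIR3DL3, at -49.3, -45.0, -35.0, -32.3, -28.2 and -25.8 percentage points. Most of these rest on wild-type replicate 2, as the 2 wild-type values were 32.6% and 72.3% at OR10H2, 14.2% and 75.8% at PRR20D, 6.60% and 58.1% at SLC38A5, 31.3% and 67.6% at GOLGA6L6 and 49.1% and 86.3% at KIR3DL3. Several belong to families of near-identical copies, whose reads cannot be told apart with certainty. Over the whole lists the lower genes were FAM236C, OR5C1, CTAG2, PNMA5, CYP11B2, ORM2, NAA10, LY6L, MAGIX and CENPVL1, from -52.5 to -45.7 percentage points. Several depend on 1 library, with CTAG2 at -22.6, NAA10 at -26.2 and CENPVL1 at -28.6 without knockout replicate 2 and PNMA5 at -15.5 without wild-type replicate 2. In the wild-type libraries CYP11B2 had 21.1% and 76.0%, and ORM2 had 55.1% and 87.4%. All of these 10 lie on chromosomes 8, 9 or X, which receive no tied peaks in the knockout lists, nor in the wild-type lists.

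As sets of peaks, the 2 genotypes did not separate beyond the spread between libraries. The Jaccard index was 0.258 for the wild-type pair and 0.266 for the knockout pair, and ran from 0.203 to 0.316 between genotypes, highest for wild-type replicate 2 with knockout replicate 1. The mean within genotypes exceeded the mean between them by 0.0127, below the between-genotype SD of 0.0505. With 2 against 2 libraries an exact permutation test cannot go below p = 0.33, so none was run. Of 269777 merged regions, 11562 were present in the 4 libraries, 5871 in both wild-type and neither knockout library, and 6478 in both knockout and neither wild-type library. Pairing each library with another of the other genotype gave 4234 and 3610, or 3050 and 9137. Among the best 20000 peaks the genotype counts were 747 and 2069, and the other pairings gave 699 and 1010, or 507 and 1800. Chromosomes 12 and 13 held 22.6% of the knockout-only and 3.05% of the wild-type-only regions of the whole lists, and 7.25% and 5.49% among the best 20000 peaks.

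Peaks common to the 2 Gibbin libraries were enriched at the ends of protein-coding genes. Of 36324 common peaks, 35.8% had their summit within 1 kb of a gene end, against 2.89% after circular shifts, a ratio of 12.4 (permutation p = 0.001, the smallest that 1000 shifts can give). A further 34.1% lay elsewhere inside genes and 30.1% between genes, and 12769 of 19970 genes (63.9%) had a common peak at an end. The reference gives no strand, so starts and ends of genes were not told apart. The replicates shared 36.8% of the peaks of replicate 1 and 34.6% of those of replicate 2, against 12.3% and 10.4% after shifts; each library alone had 14.9% and 16.7% of its peaks at gene ends. Of the peaks common to the best 20000 of each library, 62.5% lay at gene ends.

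The gene ends with the best-ranked common peaks belonged to TMEM106B, a lysosomal membrane protein (chromosome 7, 12211106 to 12212145), GOLIM4, a Golgi protein (chromosome 3, 168094972 to 168096395), ING2, a reader of methylated histone H3 (chromosome 4, 183503945 to 183505423), and EFNB2, the ephrin-B2 ligand (chromosome 13, 106533973 to 106536699). In replicate 1 their fold enrichment over the caller's background was 21.5, 19.7, 19 and 17.7, and their ranks in replicates 1 and 2 were 262 and 208, 390 and 125, 453 and 126, and 640 and 17. LYNX1 and LYNX1-SLURP2 share 1 peak, at 18.9-fold in replicate 1, as do CDCA2 and KCTD9, at 17.4-fold; TFAP4, a helix-loop-helix transcription factor, had 16.4-fold.

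Gene lists differed in how often a gene end carried Gibbin. Cohesin genes with CTCF had it at 13 of 13, led by STAG1, SMC3, PDS5B and CTCF, and ribosomal protein genes at 55 of 60 (91.7%), with RPL5, RPS2, RPL36 and RPS29 leading. Mesoderm regulators had it at 35 of 42 (83.3%), among them TWIST1, HAND1, PAX3 and TBX4, and zinc finger genes at 373 of 517 (72.1%), led by ZNF445, ZNF277, ZNF276 and ZNF326. Olfactory receptors nearly lacked it, at 4 of 390 (1.03%; OR1F1, OR2L13, OR51D1 and OR5M10), and it was less frequent in the trophoblast and amnion list, at 5 of 21 (TEAD4, CDX2, ISL1 and SDC1 among them), and in germline genes, at 11 of 28 (SMC1B, PIWIL1, TEX14 and MAEL leading). Two-sided Fisher's exact tests against the other protein-coding genes gave adjusted p = 1.1e-05 for ribosomal protein genes, 0.0236 for CTCF and cohesin, 0.0256 for mesoderm regulators, 0.000487 for zinc finger genes, 3.86e-165 for olfactory receptors, 0.00139 for trophoblast and amnion and 0.0256 for germline genes. Ribosomal protein genes had been fixed beforehand as a control list. As the control passed, passing does not by itself mark a list as a particular target of Gibbin. CpG content could not be taken into account. The zinc finger result turned with the strength of the peaks: among the best 20000 peaks of each library, 26.9% of zinc finger genes and 32.6% of other genes carried Gibbin (Fisher's exact test, adjusted p = 0.0251), and it was not past the threshold among the best 50000 (adjusted p = 0.796). The mesoderm call was lost in either library alone (Fisher's exact test, adjusted p = 0.0504 in replicate 1 and 0.257 in replicate 2). With replicate 2 alone the germline call was lost too, at 18 of 28 genes (Fisher's exact test, adjusted p = 0.540), as was that of CTCF and cohesin (adjusted p = 0.0800). At 50% reciprocal overlap only olfactory receptors of these 7 lists still passed (adjusted p from 0.257 to 0.819 for the others, with zinc finger genes at 0.870). Ribosomal protein, trophoblast and mesoderm genes did not pass in the best 20000 (adjusted p = 0.127, 0.133 and 0.133). Mesoderm genes were also lost in the best 50000 (0.0608), and CTCF and cohesin at 5 kb (0.0522). In replicate 2 alone and at 5 kb, all 13 CTCF and cohesin genes still carried Gibbin, beside 72.2% and 74.1% of other genes. Their call held in the best 20000, at 12 of 13 genes (Fisher's exact test, adjusted p = 7.71e-05). Olfactory receptors passed in every setting.

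The remaining lists did not pass Fisher's exact test at this distance and list length, though some did in other settings, such as HOX genes at 39 of 39 within 5 kb (adjusted p = 7.11e-05). Gibbin was at 31 of 39 HOX genes, 22 of 26 genes of the H3K9 methylation machinery, 18 of 22 of the DNA methylation machinery and readers, 20 of 25 neural genes and 28 of 36 genes of the BMP, WNT and retinoic acid response (adjusted p from 0.0916 to 0.160). It was at 28 of 40 surface ectoderm and epidermis genes, 13 of 19 endoderm genes, 160 of 250 zinc finger genes of chromosome 19, 32 of 53 clustered protocadherins, 16 of 27 imprinted genes, 13 of 28 mesenchyme and dermal matrix genes and 10 of 22 pluripotency genes (adjusted p from 0.135 to 1).

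**Figure D4:**
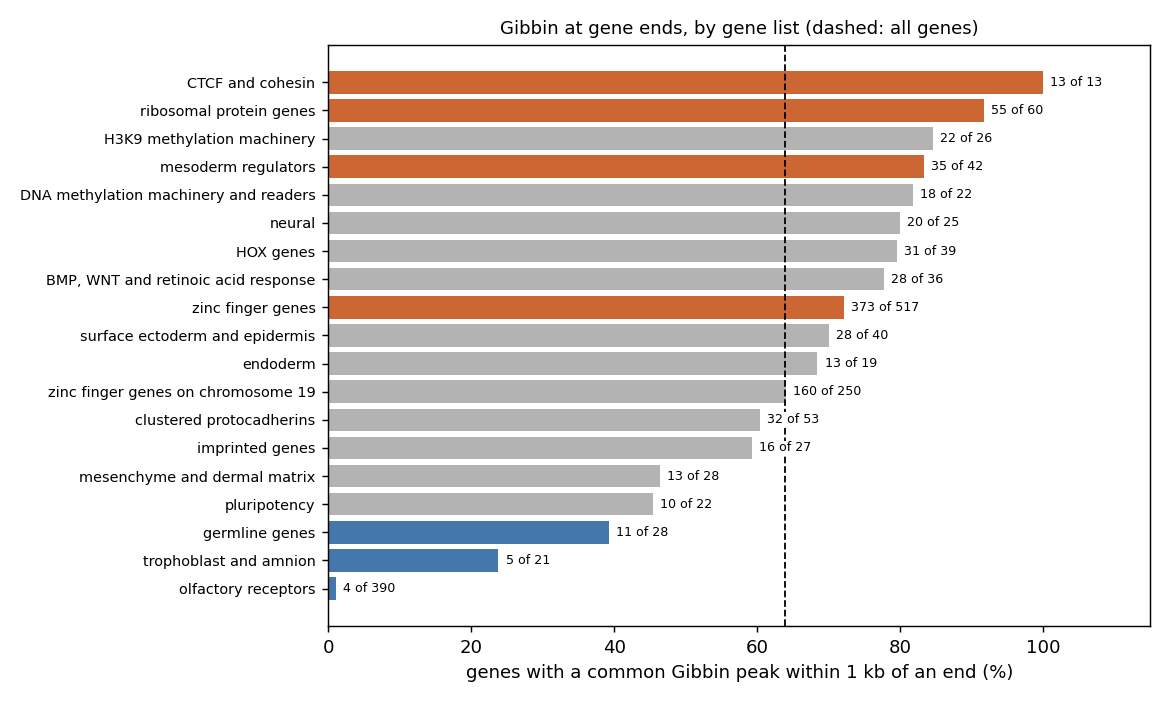
Percent of the genes of each list with a common Gibbin peak within 1 kb of an end (x axis), with counts beside the bars. Orange bars are lists above and blue bars lists below the other genes by Fisher's exact test (adjusted p under 0.05), grey bars did not pass, and the dashed line is the 63.9% of all protein-coding genes; olfactory receptors stand at 1.03% and ribosomal protein genes at 91.7%.

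Gibbin peaks also lay on H3K9me3 regions more often than shifted peaks. Of the common peaks, 9.86% overlapped a region present in both wild-type libraries, against 2.96% after shifts, a ratio of 3.33 (permutation p = 0.001, the smallest that 1000 shifts can give). The ratio was lower for all peaks of a single Gibbin library, at 2.61 for replicate 1 and 2.07 for replicate 2. Common peaks over 5 kb from every gene end overlapped at 15.1%, a ratio of 5.65, and those within 5 kb at 5.38%, a ratio of 1.68. The Gibbin libraries come from fusion-carrying cells and the H3K9me3 libraries from others, so the 2 were not measured in the same cells. The Gibbin cells were also given doxycycline for 24 hours and 5% 1,6-hexanediol, treatments that the labels of the H3K9me3 samples do not give.

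Regions present in both knockout and neither wild-type library were less often within 10 kb of a common Gibbin peak than regions present in the 4 libraries, at 18.2% against 27.4% (Cochran-Mantel-Haenszel odds ratio within width quintiles 0.589, p = 1.86e-24; permutation p = 0.005, the smallest that 200 shifts can give). Regions present in both wild-type and neither knockout library were at 25.8%, with an odds ratio of 1.02 (p = 0.654; permutation p = 0.303). Low ratios were not specific to genotype, since the 2 other pairings of the 4 libraries gave 1.11 and 0.573, and 0.640 and 1.09. Among the best 20000 peaks the ratios were 0.493 for wild-type-only and 0.426 for knockout-only regions.

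Of the genes given whatever their values, AHDC1 had a common Gibbin peak at an end, at place 9987 among gene ends ordered by mean rank, and H3K9me3 over 1.15% ± 0.164 of its length in wild type and 5.76% ± 7.14 in knockout (SD, n = 2; whole lists). These lists do not show whether the gene was disrupted, so the knockout label was not checked. CTCF stood at place 926, TWIST1 at 964, HAND1 at 2848 and GATA3 at 12705, and TP63, a regulator of epidermal fate, had no common Gibbin peak at an end. Among the best 20000 peaks, CTCF, GATA3 and HAND1 had no H3K9me3 peak in the 4 libraries.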

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

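The tests of tied peaks, of copies of chromosomes 12 and 13 and of very wide Gibbin peaks were chosen after seeing the results concerned. Those of narrower peaks, chromosome 19 and zinc finger genes with Gibbin used the best 20000 peaks, a cut chosen after seeing the data. They were therefore not wholly set before. The remaining tests below were set before. Signal outside the comparisons came from peaks that they leave out. On unplaced sequences, Gibbin replicate 1 had 858 peaks and replicate 2 had 384. The mitochondrial genome carried 1 peak in each Gibbin library, with −log10 p of 344.7 in replicate 1, where it ranked 1, and 66.7 in replicate 2, where it ranked 150; the H3K9me3 lists had none.

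Zinc finger genes were covered more in both knockout libraries among the best 20000 peaks. Tied peaks do not account for it among the best 20000 peaks, which hold none, since the lower knockout library stayed 2.97 percentage points above the higher wild-type library. Narrower peaks in wild-type replicate 1 do not account for all of it. The gap in percent of peaks was 1.07, though no gap is seen in the best 1000 or 2000 peaks. That gap is taken to wild-type replicate 2, so it does not measure what narrow peaks in replicate 1 add. By peaks replicate 1 was near replicate 2 (2.11% and 2.31%) but by length it was well below, so its widths add to the difference in length. A gain over all of chromosome 19 does not account for it either. The other genes there had a ratio of 0.892 by length, with knockout (1.57% and 1.26%) between the wild-type libraries (0.702% and 2.47%). They held fewer peaks in both knockout libraries (1.26% and 1.29% against 1.61% and 1.84%). With all tied peaks left out, which leaves 25079 peaks in knockout replicate 2 and 64220 in wild-type replicate 2, the libraries overlapped, the lower knockout value standing -1.21 percentage points from the higher wild-type value. A fixed number of peaks makes the measure relative, so a loss of strong peaks elsewhere in knockout, or a difference in depth or antibody yield, stays open, as do reads shared between related genes. The highest peak number in the names was 472823 and 611980 in wild type and 395920 and 188941 in knockout. Peaks above the ties numbered 99867 and 64220 in wild type and 46359 and 25079 in knockout. Both measures were lower in each knockout library than in either wild-type library, so yield may differ with genotype. Genotype remains a hypothesis that 2 against 2 libraries cannot settle.

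Wild-type-only and knockout-only regions of the whole lists gathered on different chromosomes. The share of knockout-only regions on chromosomes 12 and 13 fell from 22.6% to 7.25% among the best 20000 peaks, near the wild-type-only share of 5.49%, which is what the tied ends of the lists would give. More copies of these chromosomes in knockout cells are argued against by their share of the best peaks, 0.957 times that of wild type. Counts of such regions over the whole lists therefore carry little about genotype.

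Gibbin peaks lay on H3K9me3 regions above shifted peaks. Weak H3K9me3 calls at open gene ends do not account for it, since the ratio was 5.65 away from gene ends. Without peaks wider than 10 kb the ratio was 3.41, and corrected for 100 kb bins without any peak it was 3.19, which argues against wide peaks and unmapped sequence as the whole cause. Repeats and regions of high signal in any library were not tested, and may add to it; on regions of the best 20000 H3K9me3 peaks, which held 3.88% of the common peaks, lay 11.6% of the best 1000 peaks of replicate 1 and 1.90% of those of replicate 2. No biological explanation was tested.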

How the results depend on the processing

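Settings named as best 20000, best 1000, tied peaks left out, crossed pairs or width limits were chosen after seeing the data. Zinc finger genes stayed higher in knockout and past camera's threshold in 20 alternatives, and only the estimated correlation ended the call. Protocadherins did so in 19, and their call was ended also by the scaled best 20000. These 20 and 19 alternatives all kept camera's preset correlation, so they share that assumption and do not test it. They include tied peaks left out, where the libraries of the genotypes overlapped in their coverage of zinc finger genes. The germline call was lost in 10 alternatives and its sign turned, to 7.85, in the best 20000 without knockout replicate 2, where few genes are tested; the cause was not tested. Lists past camera's threshold numbered 0 with the estimated correlation and 2 in the scaled best 20000. Named H3K9me3 genes kept their side of the threshold in 903 of their values and passed it in 37; for the 39 named by size, 23 of 740 differences had the other sign.

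Wild-type-only regions numbered 2473 in the best 50000, 747 in the best 20000, 6933 with tied peaks left out and 3898 at 50% coverage, and knockout-only regions 3920 in the best 50000, 2069 in the best 20000 and 1374 with tied peaks left out. Leaving out ties shortens the knockout lists most, which lowers their count and raises the other. Leaving out each library gave 7877 to 63314 wild-type-only and 8798 to 63534 knockout-only regions, highest where 1 library then decides presence. Genes higher in knockout ranged from 0 to 10 (10 without wild-type replicate 2) and genes lower from 0 to 5 (5 without knockout replicate 1), where the lone library is assumed to vary like the others. Genes lower numbered 3 in the best 50000, 3 with no filter, 3 with tied peaks left out and 4 in the best 20000. Within the best 20000, leaving out wild-type replicate 1 gave 1 higher and 3 lower, wild-type replicate 2 gave 8 and 4, and knockout replicate 1 gave 0 and 6, with 74 zinc finger genes higher adjusted over the list alone. The replicate block gave 0 higher and 3 lower, and 0 and 3 in the best 20000; replicate numbers do not pair the libraries (correlation of same-number deviations -0.463), and crossed pairs gave 0 and 0.

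Gibbin replicate overlap, as the mean of both directions, was 39.8% in the best 50000, 7.22% at 50% reciprocal overlap, 33.8% without peaks over 10 kb, 46.6% in the best 20000 and 6.75% in the best 1000; the cause was not tested. The gene-end and H3K9me3 ratios stayed above 1 and past the threshold in all settings run. Gibbin lists past the threshold numbered 3 at 50% reciprocal overlap, 4 to 6 with each library alone, 5 in the best 20000, 8 in the best 50000, 8 without peaks over 10 kb, 9 at 5 kb and 10 within gene length quintiles, against 7. Lists passing only in some of these included HOX (5 kb and quintiles), H3K9 machinery, neural genes, protocadherins and the BMP, WNT and retinoic acid response, and as fewer the zinc finger genes of chromosome 19 (best 50000, 0.0161, and best 20000, 3.64e-06) and mesenchyme (quintiles, 0.0239). For zinc finger genes the odds ratio turned to 0.968 at 50% reciprocal overlap and to 0.762 in the best 20000; the cause was not tested. For regions only in wild type, the odds ratio near Gibbin was 0.601 in the best 50000, 0.857 at 2 kb, 1.14 at 50 kb, 0.493 in the best 20000, 0.799 with tied peaks left out, and 0.884 to 1.26 with each Gibbin library alone, so its direction depends on these choices; the ratio for knockout-only regions stayed below 1. CpG content was not run, for want of sequence. Depth is unknown, so what it limits could not be measured.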

Other observations

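The 2 Gibbin libraries differed in what led them. Their peak names carry 60 for replicate 1 and 75 for replicate 2, so their hexanediol times may differ too. The best 1000 peaks of replicate 1 were at gene ends at 31.8% and those of replicate 2 at 74.1%, and 6.30% of the former overlapped the latter. Outside the mitochondrial genome, the highest peaks of replicate 1 included 1 near LOC102724250 on chromosome 1 and others with no protein-coding gene within 2 kb, at 32916076 on chromosome 2, 125174888 and 143249372 on chromosome 1, 34580840 on chromosome 16 and 49708074 on chromosome 4. In replicate 2 they lay at CBLB, a ubiquitin ligase of immune signalling, at TCAF1, at 8256861 on chromosome 21, and between TMEM120A and STYXL1. Replicate 2 also had 51 peaks wider than 100 kb, the widest of 30003605 bp, where replicate 1 had 0.

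A hypothesis was that zinc finger genes with Gibbin at an end gain more H3K9me3 in knockout. Among the best 20000 peaks, 131 such genes with a common Gibbin peak differed by 18.1 ± 16.3 percentage points (SD over genes) and 71 without one by 12.5 ± 14.1, a difference of 5.64 (two-sided permutation test over genes, p = 0.0148). Over the whole lists the difference was 3.12 (permutation p = 0.0164), and on chromosome 19 alone, a check added afterwards like that of the whole lists, it was 4.90 and missed the threshold (permutation p = 0.0814). Neighbouring genes are not independent and share the same 4 libraries, so the p-values are too small, and a link between Gibbin and the H3K9me3 difference at these genes may be kept only as a hypothesis.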
